A study of Mus musculus with 9 samples.

How the data were processed

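Perigonadal white adipose tissue of mice of 3 genotypes was profiled on 9 Affymetrix exon arrays summarised per gene, with 3 arrays per genotype. Per the labels' protocols, total RNA was taken from snap-frozen, powdered tissue and labelled with biotin. The deposited values are log2 signals per probe set, as inferred from their range, since a 16-bit scanner cannot give these values on a natural or base 10 log scale. How the authors corrected background, summarised probes or scaled arrays is not given in the sources used here. The array medians differ, so the deposited arrays do not share 1 distribution. The genome build mm9 comes from the submitters' processing notes; no coordinates are printed because no genome of that build was used here. The series describes its replicates as biological, and names 10 samples, of which 9 were analysed here. Whether each array came from its own animal is not stated for each sample.

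Groups and replicate numbers come from the sample titles. Genes were named through a probe annotation table: of 23332 probe sets, 14996 had 1 gene symbol, 1019 had several and 7317 were not listed, among them 6577 with IDs starting 43 to 56. No source marks control probe sets, so none were left out. For lists, each of 14860 genes was represented by its brightest probe set over all arrays; 135 genes had more than 1. For Rgs5, Syne1, Socs3, Tpsb2 and Plk1, list members with several probe sets, their changes differed in size. For Tpsb2 and Plk1 they also differed in sign in some comparisons.

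The main test was limma 3.58.1 in R 4.3.3: all 9 arrays in 1 fit with a mean per genotype, empirical Bayes moderation (6 residual degrees of freedom per probe set), two-sided tests and Benjamini-Hochberg adjustment over all 23332 probe sets, with an adjusted p of 0.05 or less as the threshold. Without detection calls, low signals cannot be told from background. Gene lists for adipose functions and markers of cell types and neighbouring tissues were fixed before the data were examined. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists with at least 5 measured genes, and again with an estimated correlation. With that estimate the calls that held were skeletal muscle in both comparisons of G609G/G609G. In LCS/LCS against wt, the testis and germ cell list and the adipokine list held. The fry test asks whether a list's genes move 1 way on balance, without comparing them with other genes.

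The naming rule, also fixed before, took per comparison the 10 largest called increases and decreases without overlap of the groups, the 3 members with the smallest p in the direction of each called list, and 12 fixed genes. Predicted genes, olfactory and vomeronasal receptors, histones and immunoglobulins were skipped. Other list members named beside these were chosen after their values were seen. Each direction was checked as deposited, after quantile normalization and after median centring, which are the 3 scalings named in the text. Other alternatives were the methods' t-test, a replicate block, trended and robust moderation, array weights, filters on dim probe sets, fold minimums and leaving out each array.

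The scripts were tested on simulated data. At true log2 changes of 0.585, 1 and 2, 55.2%, 76.1% and 93.9% of the changed probe sets were recovered for G609G/G609G against wt, 52.2%, 76.1% and 100.0% for LCS/LCS against wt, and 55.2%, 74.6% and 97.0% for G609G/G609G against LCS/LCS, among 23332 probe sets. In each simulated comparison only 67, 67 and 66 probe sets were changed at these sizes. The share of false calls was 6.8%, 5.6% and 9.0%, each above the share that the adjusted p threshold aims for. The real comparisons called 12307, 4005 and 12147 probe sets, far more than were changed in the simulation. The rates therefore describe the simulated setting and do not give the recovery or the false share in the real data. Figures were drawn with matplotlib 3.10.9 and tables prepared with Python 3.11.15 and pandas 2.3.3.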

Results

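Gene expression was measured on 9 arrays of perigonadal white adipose tissue, the fat pad beside the gonads, from mice aged 4 months. There were 3 arrays each of wild type (wt), G609G/G609G and LCS/LCS mice. G609G is known as an allele of Lmna, the gene of lamins A and C, that yields the truncated lamin A progerin and models a premature ageing syndrome. The labels do not spell out LCS. Each comparison asks how the fat of 1 genotype differs from that of another. The table held 23332 probe sets, of which 14996 were paired with 1 gene symbol. These covered 14860 genes. The median signal was 6.36, 6.37 and 6.45 (log2) on the wt arrays, 5.94, 5.95 and 6.01 on the G609G/G609G arrays and 6.37, 6.31 and 6.34 on the LCS/LCS arrays. Correlations between arrays of 1 genotype were 0.992 to 0.995 for wt, 0.986 to 0.991 for G609G/G609G and 0.994 to 0.995 for LCS/LCS. Correlations between genotypes were 0.939 to 0.982. Over the 3 genotypes, 12912 probe sets differed in limma's moderated F test. All group values below are means ± SD of log2 signal with n = 3 arrays, changes carry their standard error (SE), and the number of arrays limits the precision. The p-values measure the spread between these arrays, which may be partly technical.

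Lmna itself was measured at 7.60 ± 0.04 in wt, 7.13 ± 0.12 in G609G/G609G and 7.57 ± 0.08 in LCS/LCS. Its change in G609G/G609G was -0.47 (SE 0.07, limma adjusted p = 0.000781) as deposited, 0.06 after quantile normalization and -0.05 after median centring, so it had no settled direction. The change in LCS/LCS was -0.03 (adjusted p = 0.86). A gene-level probe set does not separate the products of these alleles, so the values do not check the genotype labels.

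In G609G/G609G samples, most measured adipokine and white adipocyte genes were lower than in wt. Lep (probe set 6944966), which encodes the satiety hormone leptin, fell from 11.25 ± 0.01 to 5.32 ± 0.15, a 61.0-fold difference (log2 change -5.93, SE 0.08, adjusted p = 9.9e-10). Sfrp5, a secreted Wnt antagonist of fat, fell by 4.42, and Npr3, the natriuretic peptide clearance receptor, fell by 3.15. Adipoq, which encodes adiponectin, fell only by 0.82 (SE 0.05, adjusted p = 3.67e-06). Pparg, the master regulator of adipocyte differentiation, was 10.84 ± 0.04 against 10.96 ± 0.09 and did not pass the test as deposited (adjusted p = 0.126), but was called higher after quantile normalization (0.23) and after median centring (0.31).

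Of all 14860 genes in this comparison, 7944 were called lower and 1560 higher as deposited. After quantile normalization 4388 were lower and 4237 higher, after median centring 4108 and 6517, and under all 3 scalings 3790 and 1522. The member counts of every list in this comparison are to be read beside these counts. Of 17 measured white adipocyte identity genes, 15 fell and 1 rose, with the same counts adjusted over the list alone, and 11 of the falls held under all 3 scalings. Their median change was -0.68 (camera adjusted p = 0.002, adjusted p = 0.312 with an estimated correlation). Rbp4 fell by 1.75, while Slc2a4, the insulin-responsive glucose transporter, rose by 0.51. Among 21 adipokine and fat-mass-linked genes, 15 fell and 3 rose, also 15 and 3 adjusted over the list alone, and 13 and 3 held under all 3 scalings (camera adjusted p = 0.0204, adjusted p = 0.273 with an estimated correlation, and adjusted p = 0.0557 without G609G/G609G replicate 3). Sncg fell by 2.90 and Itih5 by 1.67. The lists of lipogenesis and lipolysis genes did not pass the list test (camera adjusted p = 0.0914 and 0.0951). Of their members, 18 of 24 and 8 of 11 fell, 17 and 8 of them under all 3 scalings. Fasn, the fatty acid synthase, fell by 2.04 (SE 0.05, adjusted p = 3.75e-08), and Dgat2, which makes triglyceride, fell by 2.82. Scd1, a fatty acid desaturase, fell by 0.29 as deposited and was 0.13 after median centring. On the same arrays all 12 skeletal muscle markers were higher, with a median change of 6.21. Wnt signalling genes had 12 falls and 1 rise among 18, counts that were the same adjusted over the list alone, and 9 falls and 1 rise held under all 3 scalings (camera adjusted p = 0.0497, adjusted p = 0.273 with an estimated correlation). That call was lost with a filter on the dimmest probe sets (adjusted p = 0.177) and without wt replicate 1 or 2 (0.0558 and 0.0729), G609G/G609G replicate 3 (0.0614) or LCS/LCS replicate 1 or 2 (0.0505 and 0.0511).

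**Figure D1:**
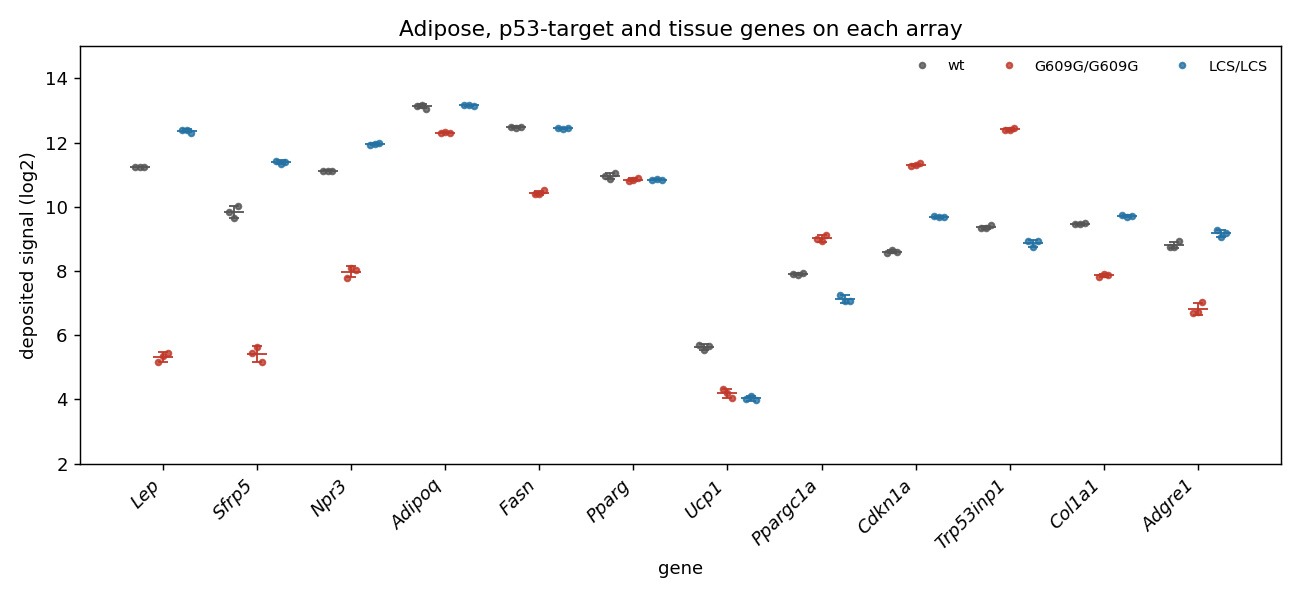
Deposited signal (log2, vertical axis) of 12 genes on each of the 9 arrays, with points for arrays, a dash for the group mean and bars for the SD (n = 3). Lep lies near 5.32 in G609G/G609G, 11.25 in wt and 12.37 in LCS/LCS, while Pparg lies between 10.84 and 10.96 in all 3 genotypes as deposited, though its change in G609G/G609G is 0.23 after quantile normalization.

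Several p53 targets and most measured genes of the fasting response were higher in G609G/G609G samples. Cdkn1a, the p21 cell cycle inhibitor, rose from 8.60 ± 0.05 to 11.31 ± 0.04 (log2 change 2.71, SE 0.05, adjusted p = 6.75e-09). Trp53inp1 rose by 3.05, Sesn1 by 2.17, Gadd45b by 2.45 and Eda2r by 1.33, whereas Phlda3 fell by 1.35 and Perp by 1.05. In all, 8 of 26 measured p53 and senescence genes rose and 11 fell as deposited, and 8 and 12 did so adjusted over the list alone. After quantile normalization 14 rose and 6 fell, after median centring 15 and 5, and 8 rises and 5 falls held under all 3 scalings. The list's median was -0.09 and its mean 0.28, and camera, which compares a list with all other genes, placed it above them (adjusted p = 0.00981, adjusted p = 0.281 with an estimated correlation and adjusted p = 0.0921 after median centring). Of 15 genes of the glucocorticoid and fasting response, 12 rose and 3 fell, also when adjusted over the list alone, and all 12 rises held under all 3 scalings (median 1.03, camera adjusted p = 3.16e-10, adjusted p = 0.15 with an estimated correlation). Fbxo32, a ubiquitin ligase of muscle wasting, rose by 3.45, Errfi1 by 2.33 and Pdk4, which spares glucose in fasting, by 1.51. Angptl4 and Lcn2 of the same list fell, by 0.36 (a call lost under both other scalings) and 1.71. On the same arrays the skeletal muscle marker list had a median change of 6.21, and muscle also expresses Fbxo32, Pdk4, Cdkn1a and Slc2a4. Whether these or the other rises of this paragraph came from fat or from muscle was not tested.

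Skeletal muscle genes made up the 10 largest rises that the naming rule took. Atp2a1, the calcium pump of fast muscle fibres, went from 4.74 ± 0.03 to 12.62 ± 0.06 (log2 change 7.88, SE 0.08, adjusted p = 2.97e-10). Tnnt3 rose by 7.75, Pvalb by 7.16 and Ckm, the muscle creatine kinase, by 6.30. All 12 measured muscle markers rose, also adjusted over the list alone, and the list was called with the preset correlation (camera adjusted p = 2.44e-23) and with an estimated correlation (adjusted p = 0.0316). Desmin (Des), of muscle in general, rose by 2.75, and the pericyte and smooth muscle list that holds it had 5 rises and 3 falls among 12, or 6 and 5 adjusted over the list alone and 9 and 3 under either other scaling (camera adjusted p = 0.0163, adjusted p = 0.459 with an estimated correlation and 0.0876 after median centring).

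Among thermogenic genes, Ppargc1a, a coactivator that drives mitochondrial genes, rose by 1.11 (SE 0.08, adjusted p = 6.47e-06) and Cox8b, a respiratory subunit of muscle and brown fat, by 2.24, beside the rise of the muscle list by 6.21. Ucp1, the uncoupling protein of brown fat, was low in every genotype and fell from 5.63 ± 0.08 to 4.19 ± 0.14. The brown and beige list had 7 rises and 7 falls among 21 as deposited, or 7 and 9 adjusted over the list alone, 13 rises and 3 falls after quantile normalization and 15 and 3 after median centring (camera adjusted p = 0.0115 upwards, adjusted p = 0.273 with an estimated correlation). Markers of brown fat depots had 2 rises and 2 falls among 10 as deposited, the same adjusted over the list alone, 6 and 1 after quantile normalization and 8 and 1 after median centring (camera adjusted p = 0.0453 upwards, adjusted p = 0.273 with an estimated correlation). This call was lost after median centring (adjusted p = 0.077) and without wt replicate 3 (0.0619) or G609G/G609G replicate 3 (0.059). The depot list's median was 0.01, and 6 of its 10 members are on another list as well. Ucp1 and Cox8b, for example, are also on the brown and beige list, so the calls of these lists are not independent. In wt, 4 of the 10 lay above the array median. Centring added 0.425 to every change, so rises of dim members after it may come from that shift. The respiratory chain list was not called (adjusted p = 0.648), and its direction turned with scaling: 1 of 36 genes rose and 10 fell as deposited, 27 and 3 after quantile normalization and 28 and 2 after median centring. Among clock genes, Nfil3 rose by 3.29, Npas2 by 2.06 and Arntl by 1.48, while Bhlhe41 fell by 2.32. Of 13 clock genes, 5 rose and 5 fell as deposited, also adjusted over the list alone, against 9 and 3 after quantile normalization and 9 and 4 after median centring (median -0.05, mean 0.23, camera adjusted p = 0.0497 upwards, adjusted p = 0.693 with an estimated correlation). That call was lost after median centring (adjusted p = 0.17) and without wt replicate 1 or 2 (0.0614 and 0.0625), G609G/G609G replicate 2 or 3 (0.0508 and 0.0614) or LCS/LCS replicate 2 (0.0511). Igfbp3 led the insulin signalling list with a rise of 2.74; 6 of its 16 genes rose and 4 fell as deposited, also adjusted over the list alone, against 13 and 1 after quantile normalization and 12 and 1 after median centring (median -0.01, mean 0.20, camera adjusted p = 0.00981 upwards, adjusted p = 0.575 with an estimated correlation). The medians of the insulin, clock, p53 and endothelial lists lay just below 0 as deposited and above 0 under both other scalings.

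Most measured genes of matrix, fibroblasts and macrophages were lower in G609G/G609G samples, in which the skeletal muscle list was higher by a median of 6.21. Col3a1 and Col1a1, fibrillar collagens, fell by 1.99 and 1.61, and Thbs1, an adhesive glycoprotein, by 2.41. Of 27 extracellular matrix genes, 23 fell and 1 rose, the same adjusted over the list alone, and 20 falls held under all 3 scalings (median -1.15, camera adjusted p = 0.000775, adjusted p = 0.312 with an estimated correlation). Of 15 progenitor and fibroblast markers, 14 fell, the same adjusted over the list alone, and 10 falls held under all 3 scalings (camera adjusted p = 0.00619, adjusted p = 0.281 with an estimated correlation). Of 15 macrophage markers, 14 fell, or 15 adjusted over the list alone, and 9 falls held under all 3 scalings (median -1.28, camera adjusted p = 0.00301, adjusted p = 0.273 with an estimated correlation). Adgre1, which encodes the macrophage antigen F4/80, fell by 2.00 (SE 0.10, adjusted p = 1.52e-06), and Csf1r fell by 1.48. Ccl2, a monocyte chemoattractant, fell by 0.68, a call that quantile normalization ended (-0.19, adjusted p = 0.164). Cell cycle genes had 18 falls among 22, or 19 adjusted over the list alone, of which 9 held under all 3 scalings, and after median centring 9 fell and 4 rose (camera adjusted p = 0.042, adjusted p = 0.306 with an estimated correlation), and E2f1 fell by 1.29. That list call was lost after median centring (adjusted p = 0.0876), with a filter on the dimmest probe sets (0.157) and without G609G/G609G replicate 3 (0.063). Neutrophil markers had 6 rises and 1 fall among 11, also adjusted over the list alone, and the 6 rises held under all 3 scalings (camera adjusted p = 0.000775, adjusted p = 0.273 with an estimated correlation), at low signals such as 4.92 ± 0.02 for S100a9. Endothelial markers had 6 rises and 6 falls among 18 as deposited, also adjusted over the list alone, but 13 rises and 0 falls after quantile normalization and 14 and 0 after median centring. Camera placed them above other genes although their median was -0.08 and their mean -0.02 (adjusted p = 0.0445, adjusted p = 0.693 with an estimated correlation). That call was lost without wt replicate 2 (adjusted p = 0.0729) or G609G/G609G replicate 3 (0.0778).

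Most measured transcripts of the male reproductive tract were lower in G609G/G609G samples than in wt. Lcn8, an epididymal lipocalin, fell from 12.82 ± 0.01 to 4.08 ± 0.05 (log2 change -8.74, SE 0.05, adjusted p = 3.05e-11). Gpx5, an epididymal peroxidase, fell from 13.40 ± 0.02 to 5.40 ± 0.79, and Cst11 fell by 6.12. Of 18 epididymal markers, 14 fell and 1 rose, also adjusted over the list alone, with 12 falls and 1 rise under all 3 scalings (camera adjusted p = 0.002, adjusted p = 0.293 with an estimated correlation). Of 16 testis and germ cell markers, 15 fell, also adjusted over the list alone, with 11 falls under all 3 scalings (camera adjusted p = 0.00414, adjusted p = 0.293 with an estimated correlation). This list, called the germ cell list below, also holds testis genes that are not sperm genes, such as Cyp17a1. Prm1, a sperm protamine, fell by 1.72.

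Across all probe sets, 12307 differed between G609G/G609G and wt at an adjusted p of 0.05 or less, 2195 higher and 10112 lower. The direction of this split depended on scaling, since 17.8% of the calls were higher as deposited, 51.0% after quantile normalization and 65.8% after median centring; 2138 rises and 4610 falls held under all 3. The median change over all probe sets was -0.227 as deposited, 0.017 after quantile normalization and 0.198 after median centring. With a fold of at least 1.5 as well, 6934 passed.

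In LCS/LCS samples, most measured adipokine and extracellular matrix genes were higher than in wt. Of 16 testis and germ cell markers, 15 were lower (median -2.43). Lep rose from 11.25 ± 0.01 to 12.37 ± 0.05, a 2.17-fold difference (log2 change 1.12, SE 0.08, limma adjusted p = 3.7e-05). Pnpla3, a lipid-droplet enzyme, rose by 1.12, Sfrp5 by 1.56, Trp53inp2 by 0.93 and Npr3 by 0.83. Ucp1 fell from an already low 5.63 ± 0.08 to 4.03 ± 0.08 (SE of the change 0.08, adjusted p = 8.08e-06), and Ppargc1a fell by 0.77 (SE 0.08, adjusted p = 0.000277). Cdkn1a rose by 1.09 (SE 0.05, adjusted p = 3.79e-06). Adipoq (0.03, adjusted p = 0.757), Fasn (-0.02, adjusted p = 0.843) and Scd1 (0.01, adjusted p = 0.908) did not pass the test. Pparg did not pass it as deposited (-0.12, adjusted p = 0.257) and was called lower after quantile normalization (-0.18, adjusted p = 0.0345).

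Of 21 adipokine and fat-mass-linked genes, 15 rose and none fell, on arrays where the germ cell list had a median change of -2.43 and the liver list of -0.65. The 15 rises were the same in number adjusted over the list alone and held under all 3 scalings (median 0.35, camera adjusted p = 5.89e-07, adjusted p = 0.0465 with an estimated correlation). White adipocyte identity genes had 8 rises among 17, or 10 rises and 1 fall adjusted over the list alone and 8 rises under all 3 scalings (camera adjusted p = 0.00585, adjusted p = 0.416 with an estimated correlation, and adjusted p = 0.081 after quantile normalization). The glucocorticoid and fasting list had 12 rises and 1 fall among 15, also adjusted over the list alone, and 11 and 1 under all 3 scalings (median 0.40, camera adjusted p = 1.98e-05, adjusted p = 0.248 with an estimated correlation). Within it, Tsc22d3 rose by 0.65, Pdk4 by 0.61 and Angptl4, an inhibitor of lipoprotein lipase, by 0.51. Fatty acid oxidation genes had 6 rises among 21, or 10 adjusted over the list alone and 4 under all 3 scalings (camera adjusted p = 0.0299, adjusted p = 0.502 with an estimated correlation). Lipolysis genes had 3 rises among 11, or 6 adjusted over the list alone and 2 under all 3 scalings (camera adjusted p = 0.0379, adjusted p = 0.335 with an estimated correlation). Insulin signalling genes had 7 rises and 1 fall among 16, or 8 and 1 adjusted over the list alone and 7 and 1 under all 3 scalings (camera adjusted p = 0.041, adjusted p = 0.608 with an estimated correlation). Quantile normalization ended the calls of the fatty acid oxidation, lipolysis and insulin lists (adjusted p = 0.289, 0.14 and 0.185), as did a filter on the dimmest probe sets (0.0747, 0.0768 and 0.0861). The lipolysis call was also lost without LCS/LCS replicate 2 (0.0531), and the insulin call without wt replicate 2 (0.0607), G609G/G609G replicate 1 (0.0509) or LCS/LCS replicate 1 (0.0588).

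Most measured extracellular matrix genes were higher in LCS/LCS samples, in which the germ cell list had a median change of -2.43 and the liver list of -0.65. The basement membrane collagens Col4a2 and Col4a1 rose by 1.20 and 0.78, and Col6a2 rose by 0.82. Of 27 extracellular matrix genes, 22 rose and 1 fell, the same adjusted over the list alone and under all 3 scalings (median 0.47, camera adjusted p = 1.08e-09, adjusted p = 0.248 with an estimated correlation). Macrophage markers had 9 rises and 1 fall among 15, or 11 and 1 adjusted over the list alone and 8 and 1 under all 3 scalings (camera adjusted p = 0.0012, adjusted p = 0.248 with an estimated correlation). Mmp12, the macrophage elastase, rose by 1.09 and Cd163 by 0.77. Adgre1 rose by 0.36 (adjusted p = 0.0495), a call that leaving out any of 8 of the 9 arrays ended, at an adjusted p of up to 0.164. Col1a1 rose by 0.24 (adjusted p = 0.0152), a call lost without wt replicate 1 or 2 (0.0601 and 0.0597) or LCS/LCS replicate 1 or 3 (0.0685 and 0.0527). Ccl2 rose by 0.59 (adjusted p = 0.00192). Endothelial markers had 12 rises among 18, or 13 adjusted over the list alone (camera adjusted p = 0.000133, adjusted p = 0.416 with an estimated correlation), led by Lyve1 at 0.79. Mesothelial markers had 8 rises and 1 fall among 11, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.416 with an estimated correlation). Progenitor markers had 8 rises among 15, or 9 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.335 with an estimated correlation, and adjusted p = 0.0849 after quantile normalization). Antigen presentation genes of class II had 5 rises among 9, also adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.248 with an estimated correlation), and H2-Ab1 rose by 0.55.

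Most measured testis and germ cell transcripts were lower in LCS/LCS samples than in wt. Prm2, a sperm protamine, fell by 4.29 and Ldhc, the lactate dehydrogenase of sperm, by 4.17. Cyp17a1, a testis gene of the same list, changed by -3.84 to -3.71 when each array was left out in turn. Of 16 testis and germ cell markers, 15 fell, also adjusted over the list alone and under all 3 scalings (median -2.43, camera adjusted p = 2.7e-19, adjusted p = 0.0465 with an estimated correlation). Spint4 fell from 12.94 ± 0.03 to 4.68 ± 0.54 (log2 change -8.26, SE 0.22, adjusted p = 2.03e-07) and the defensin Defb38 fell by 6.11. The epididymal list was not called (median 0.08, mean -0.02, adjusted p = 0.998), with 6 rises and 4 falls among 18, or 6 and 5 adjusted over the list alone: Rnase10 rose by 1.43 and Spink8 fell by 2.16. Of 12 muscle markers, 4 rose, or 7 adjusted over the list alone, led by Acta1 at 1.51 (camera adjusted p = 0.0442, adjusted p = 0.433 with an estimated correlation, and adjusted p = 0.0838 after median centring). That call was also lost with a filter on the dimmest probe sets (0.0861) and without wt replicate 3 (adjusted p = 0.157), G609G/G609G replicate 1, 2 or 3 (0.0617, 0.0538 and 0.0765) or LCS/LCS replicate 1 or 2 (0.0682 and 0.0681). Liver markers had 6 falls among 7, or 6 falls and 1 rise adjusted over the list alone, and Alb, which encodes albumin, fell by 3.03 (camera adjusted p = 0.000101, adjusted p = 0.215 with an estimated correlation). Erythroid markers had 2 falls among 5, or 3 adjusted over the list alone, and Alas2, of haem synthesis, fell by 1.06 (camera adjusted p = 0.0442, adjusted p = 0.248 with an estimated correlation, and adjusted p = 0.14 after quantile normalization). The erythroid call was also lost without wt replicate 2 (0.0786), G609G/G609G replicate 2 (0.0538) or LCS/LCS replicate 1 or 2 (0.0588 and 0.0681). Among the genes that the naming rule took, the largest rises were Slc5a7, the choline transporter, at 2.49, and Sectm1b at 2.18.

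**Figure D2:**
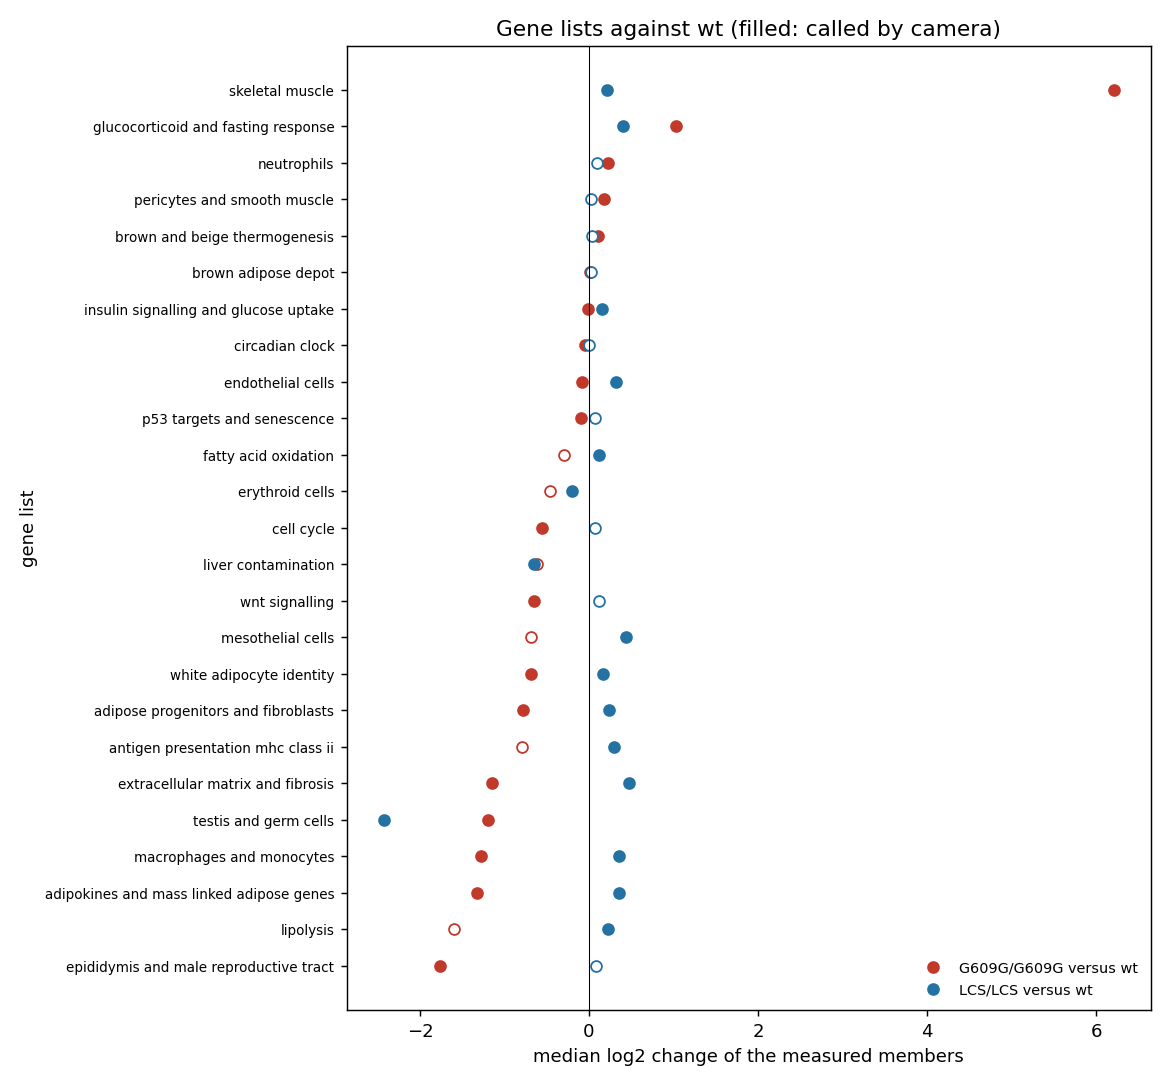
Median log2 change of the measured members of each gene list (horizontal axis) in both comparisons with wt, for lists called in either comparison, with filled points for lists called by camera. The skeletal muscle list lies at 6.21 in G609G/G609G, and the extracellular matrix list lies at -1.15 in G609G/G609G and 0.47 in LCS/LCS.

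For LCS/LCS against wt, 4005 probe sets passed, 2194 higher and 1811 lower; 2061 rises and 1592 falls held under all 3 scalings. Higher calls made up 54.8% as deposited, 53.8% after quantile normalization and 67.7% after median centring. With a fold of at least 1.5 as well, 1385 passed, without LCS/LCS replicate 3 the count was 2669, and with array weights it was 6511.

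Set directly against LCS/LCS, the G609G/G609G samples had lower values of most measured adipokine, white adipocyte and extracellular matrix genes and higher values of all 12 muscle markers. Lep was 132.5-fold lower (log2 change -7.05, SE 0.08, adjusted p = 4.29e-10), Sfrp5 fell by 5.98 and Fasn by 2.01. Cdkn1a was higher by 1.62 and Ppargc1a by 1.88, beside a muscle list median of 6.09 with all 12 markers higher, also adjusted over the list alone (camera adjusted p = 4.75e-21, adjusted p = 0.0415 with an estimated correlation). Ucp1 (0.16, adjusted p = 0.158) did not pass the test as deposited and was called higher after median centring (0.53) and without G609G/G609G replicate 3 (0.23). Adipoq fell by 0.85, Ccl2 by 1.26, Adgre1 by 2.37 and Col1a1 by 1.85. As deposited Lmna fell by 0.44, Scd1 by 0.30 and Pparg did not pass the test (adjusted p = 0.969), but Lmna was 0.09 and Pparg 0.41 after quantile normalization, and Scd1 was 0.07 and Pparg 0.37 after median centring. Of all 14860 genes, 7588 were called lower and 1673 higher in this comparison as deposited, and 3900 and 1613 under all 3 scalings. Of 27 extracellular matrix genes, 23 fell and 1 rose, the same adjusted over the list alone (median -1.64, camera adjusted p = 2.2e-05, adjusted p = 0.289 with an estimated correlation), and 22 falls held under all 3 scalings. All 15 macrophage markers fell, also adjusted over the list alone, and 12 did so under all 3 scalings (camera adjusted p = 0.00033, adjusted p = 0.152 with an estimated correlation). Of 16 testis and germ cell markers, 12 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 1.65e-08, adjusted p = 0.104 with an estimated correlation), led by Odf1 at 4.05. Counts for the other called lists were the same adjusted over the list alone unless given. White adipocyte genes had 15 falls among 17 (camera adjusted p = 0.000615, adjusted p = 0.298 with an estimated correlation), adipokine genes 15 falls and 1 rise among 21 (0.00082, adjusted p = 0.104 with an estimated correlation) and lipolysis genes 10 falls and 1 rise among 11 (0.0237, adjusted p = 0.289 with an estimated correlation). Progenitor markers had 14 falls among 15 (camera adjusted p = 0.00135, adjusted p = 0.211 with an estimated correlation), and mesothelial markers 9 among 11, or 11 adjusted over the list alone (0.0153, adjusted p = 0.606 with an estimated correlation). Wnt genes had 13 falls among 18 (camera adjusted p = 0.0155, adjusted p = 0.131 with an estimated correlation), and cell cycle genes 17 among 22, or 18 adjusted over the list alone (0.0309, adjusted p = 0.298 with an estimated correlation). Fasting genes had 12 rises and 3 falls among 15 (camera adjusted p = 4.83e-07, adjusted p = 0.12 with an estimated correlation). Placed above other genes were the thermogenic list with 6 rises and 4 falls among 21 (0.00143, adjusted p = 0.104 with an estimated correlation), the brown depot list with 4 and 1 among 10 (0.000921, adjusted p = 0.104 with an estimated correlation), the clock list with 6 and 4 among 13 (0.0295, adjusted p = 0.624 with an estimated correlation) and the neutrophil list with 4 and 3 among 11 (0.0153, adjusted p = 0.295 with an estimated correlation). Under all 3 scalings 13 falls of the white adipocyte, 14 of the adipokine, 8 of the lipolysis, 11 of the progenitor, 7 of the mesothelial, 10 of the Wnt and 11 of the cell cycle list held. After median centring the thermogenic list had 16 rises and 2 falls, the brown depot list 9 and 0, the clock list 9 and 4 and the neutrophil list 8 and 0. Centring added 0.373 to every change in this comparison, and 6 of the 10 brown depot markers are on another list as well. The clock and cell cycle calls were lost after median centring (0.17 and 0.0538), the neutrophil call after quantile normalization (0.236), and the lipolysis, cell cycle and Wnt calls with a filter on the dimmest probe sets (0.0648, 0.0965 and 0.0635).

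In total 12147 probe sets passed, 2400 higher and 9747 lower. Higher calls made up 19.8% as deposited, 50.4% after quantile normalization and 61.7% after median centring, and 2317 rises and 4766 falls held under all 3 scalings.

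**Figure D3:**
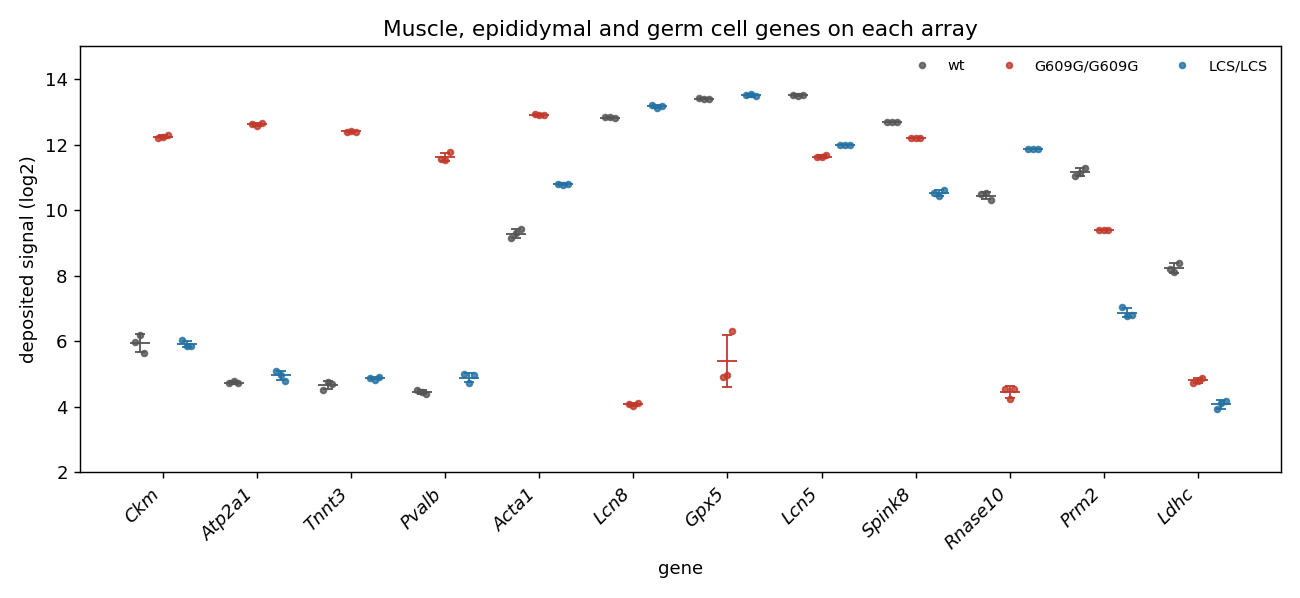
Deposited signal (log2, vertical axis) of muscle, epididymal and germ cell genes on each of the 9 arrays, with points for arrays, a dash for the group mean and bars for the SD (n = 3). Ckm lies at 12.24 in G609G/G609G against 5.94 in wt, Lcn8 at 4.08 in G609G/G609G against 12.82 in wt, and Prm2 at 6.87 in LCS/LCS against 11.16 in wt.

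The genes that changed in both mutant genotypes against wt split in both ways. Lep, Sfrp5 and Col6a2 were among the opposed, Cdkn1a and Pdk4 among those higher in both, and the sperm gene Ldhc among those lower in both. Lower in G609G/G609G and higher in LCS/LCS were 1601 probe sets, where independent lists would share 950.9. All 1601 also passed in the direct comparison, but opposed changes add up in that contrast of the same fit. Their passing was therefore fixed in advance and adds no support. Lower in both were 1497 (784.9 for independent lists), higher in both 243 (206.4) and higher in G609G/G609G but lower in LCS/LCS 119 (170.4). That baseline takes all 23332 probe sets as equally likely to be called, dim ones included. Both the opposed 1601 and the 1497 lower in both exceed it, so the excess does not show that opposed changes are favoured. Leaving out wt replicate 1 or 2 or LCS/LCS replicate 1 or 3 brought the opposed count of 1601 to 971, 980, 983 and 1001, and leaving out LCS/LCS replicate 1 or 3 brought the count higher in both to 147 and 155. Quantile normalization changed the count higher in both to 748 and the count higher in G609G/G609G but lower in LCS/LCS to 465. It changed the opposed count of 1601 to 1190 and the count lower in both to 1337. Both comparisons share the wt arrays, which in 100 simulations of unchanged groups gave a correlation across probe sets of 0.499, against 0.169 observed. The lower observed value does not show less sharing than in unchanged groups, since real changes add variance that those groups lack. Probe sets are not independent replicates. The covariance of the changes was 0.0494 against 0.0140 simulated, a difference of 0.0354.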

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

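Of the alternatives, only the restriction to probe sets with 1 gene symbol was chosen after seeing the data; it gave 10148, 4055 and 9821 probe sets for G609G/G609G versus wt, LCS/LCS versus wt and G609G/G609G versus LCS/LCS. Calls depended mostly on fold minimums, scaling and the correlation used for lists. With a fold of at least 1.5 as well, 6934, 1385 and 7184 probe sets passed, in the same order; with the submitters' fold and unadjusted p applied to limma 7112, 1599 and 7357 passed, and with the methods' t-test at that threshold 6650, 1487 and 6933 (9808, 4019 and 10264 after Benjamini-Hochberg adjustment instead). These stricter fold limits by construction remove small changes. Array weights gave 6511 for LCS/LCS versus wt, and the cause was not tested. Higher calls were 51.0% and 50.4% after quantile normalization and 65.8% and 61.7% after median centring for the 2 comparisons of G609G/G609G, and 67.7% after centring for LCS/LCS versus wt. Centring adds a constant to every change, 0.425 for G609G/G609G versus wt, 0.373 versus LCS/LCS and 0.052 for LCS/LCS versus wt. The cause of the shares after quantile normalization was not tested. Called lists numbered 1, 2 and 1 with an estimated correlation, and 35, 28 and 37 with fry, which tests another hypothesis; quantile normalization gave 25 for G609G/G609G versus LCS/LCS. After quantile normalization the overlaps were 748 higher in both and 465 higher in G609G/G609G and lower in LCS/LCS; the cause was not tested. Lmna was 0.06 and 0.09 after quantile normalization in G609G/G609G versus wt and versus LCS/LCS, and was no longer called. Pparg was 0.23 and 0.41 after it and 0.31 and 0.37 after centring, and became called. Scd1 was 0.13 and 0.07 after centring and was no longer called. The cause was not tested. Leaving out each array in turn gave 2669 to 4805 probe sets for LCS/LCS versus wt, 147 to 268 higher in both, and 971 to 2048 lower in G609G/G609G and higher in LCS/LCS; the upper ends came without G609G/G609G replicate 3, and the cause was not tested. Of 2899 recalculations of 223 named changes, 2850 kept their side of the threshold, and their sign where called. Uncalled changes near 0 could turn in sign among these. Another 34 lost the call, 7 gained it and 8 turned in sign with a call lost or gained. In these 8, Lmna and Scd1 lost the call and Pparg gained it, so no call became an opposite call. Of 815 recalculations for the 51 called lists, 707 were kept and 108 lost the call, 47 of these with the estimated correlation. Correlations of same-numbered deviations were 0.08 to 0.23, -0.07 to 0.08 and -0.07 to 0.08, and 3, 1 and 1 of 3 arrays matched their own number best. Replicate numbers thus did not pair the arrays in the comparisons with LCS/LCS. For G609G/G609G versus wt the correlations were low, but pairing is not excluded. The replicate block gave 17, 15 and 17 called lists, without the Wnt and clock lists of G609G/G609G versus wt (adjusted p = 0.0659 and 0.053) and the muscle list of LCS/LCS versus wt (0.0613). The linear-scale alternative was not run, since the values are logarithmic. Depth does not apply to arrays; signals near the lowest quartile, about 4.33 to 4.41, have no measured background.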

Other observations

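Several gene groups were left aside in the comparisons. In G609G/G609G against wt, 7944 of all 14860 genes were called lower, 3790 of them under all 3 scalings. Interferon response genes had 12 falls and 1 rise among 15, or 7 falls and 1 rise under all 3 scalings, and the list was not called (camera adjusted p = 0.152). Liver markers had 7 falls among 7, or 3 under all 3 scalings, with a median of -0.62, and were not called either (camera adjusted p = 0.0632). Unfolded protein and stress genes had 13 falls and 6 rises among 21 as deposited but 9 and 8 after quantile normalization (adjusted p = 0.997), and antigen presentation genes of class II had 5 falls among 9, all 5 under all 3 scalings, and 4 rises after median centring (adjusted p = 0.45). Of the T and NK cell, B cell and pancreas markers, 5 of 14, 3 of 11 and 1 of 9 fell and 0 rose as deposited (camera adjusted p = 0.997, 0.742 and 0.111). After quantile normalization 1, 0 and 2 rose and 2, 2 and 0 fell, and after median centring 8, 8 and 7 rose and 1, 2 and 0 fell. Centring added 0.425 to every change. The 10th percentile of signal was already alike before it, 3.54 to 3.58 in wt and 3.55 to 3.61 in G609G/G609G. Rises of dim genes after centring may therefore come from that shift. In LCS/LCS against wt, p53 and senescence genes had 6 rises and 1 fall among 26 (adjusted p = 0.112), with Ddit4 at 0.91 and Phlda3 at 0.72, and inflammatory genes had 7 rises and 1 fall among 25 (adjusted p = 0.0779).

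All tests below were chosen after the results were seen. Skeletal muscle genes were far higher in G609G/G609G than in wt. All 12 measured markers were at least 4-fold higher under all 3 scalings, none is on another list, 2 lay above the wt array median in wt, and Atp2a1, Tnnt3 and Ckm reached 12.62, 12.40 and 12.24. Scaling is argued against by size, since the lowest list median over the scalings was 6.21 while centring added only 0.425 to every change. With so small a shift the retest could hardly have ended otherwise. For brown fat cells, the change of Ucp1 nearest to 0 was -1.01. This 1 gene was low in every genotype, while Cox8b rose and the thermogenic and brown depot lists were called upwards. It therefore cannot decide on brown fat cells. Skeletal muscle carried into these samples and muscle gene expression by the fat tissue of this genotype cannot be told apart, since the count of 12 restates the pattern and no muscle reference was measured.

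Epididymal and germ cell genes differed between all 3 genotypes. A single tissue share that varied in amount is argued against, since 6 epididymal markers rose and 4 fell in LCS/LCS against wt under all 3 scalings (the test value is the smaller, 4, for one share of one reproductive tissue that differs in amount). Scaling is argued against by the size of the germ cell list's change, since its median nearest to 0 was -2.33 while centring added only 0.052 to every change. With so small a shift this retest too could hardly have ended otherwise. Lcn8, Gpx5 and Rnase10 were low in G609G/G609G and high in wt and LCS/LCS, whereas Spint4 and Defb38 were low only in LCS/LCS among the 3 genotypes. Different parts of the epididymis in the samples of each genotype may fit this, and so may the genotype itself; no segment reference was used.

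Arrays of 1 genotype were nearly alike over all probe sets, and so was their mean of neighbouring-tissue markers, though single markers such as Gpx5 varied. That mean pools muscle, epididymal and germ cell markers, so opposite shifts of different tissues could cancel in it. The SD between arrays of the mean of muscle, epididymal and germ cell markers at 7 or more was 0.027 in wt, 0.049 in G609G/G609G and 0.023 in LCS/LCS. These SDs lay at percentiles of 32.4, 74.5 and 70.3 among 10000 level-matched random lists; without members above 11, a limit added after those percentiles were seen, they lay at 52.1, 68.0 and 91.0, the last from 7 markers. Separate dissections that carried differing amounts of such tissue and RNA shared by the arrays of a genotype cannot be told apart, since percentiles under 95 from so few markers and arrays do not show equal amounts. The series describes biological replicates, and Gpx5 varied between G609G/G609G arrays with an SD of 0.79; whether the arrays may share RNA stays open, so the p-values may not cover variation between animals.

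Other splits of the same arrays were counted. The real grouping gave 12307 probe sets for G609G/G609G against wt, 4005 for LCS/LCS against wt and 12147 for G609G/G609G against LCS/LCS, and the highest other split gave 1, 0 and 0. The 10 splits in each case are too few for a share under 0.05. For the test over 3 genotypes, 1 of 100 splits drawn, the real one, reached 12912, and the highest other gave 9927. The real labels thus gave the highest count of the splits drawn. With another split at 9927, that rank does not show that each pair of genotypes differs. It also does not cover chance differences between animals, since RNA shared by the arrays of a genotype was left open.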
